A study of Gallus gallus with 6 samples.

How the data were processed

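Total RNA from 6 samples of the chicken B cell line DT40, 3 wild type and 3 Pax5-deficient, was labelled with biotin and hybridised to Affymetrix chicken arrays. Samples were grouped by the genotype and title in the labels. Per the labels' protocols, the PAX5 gene was targeted with constructs that carry neomycin and blasticidin selection cassettes, and stably transfected clones were selected. The labels do not say whether the 3 Pax5-deficient samples share a clone. The text of the RNA extraction protocol also names Bcl6-deficient DT40 cells, which are not analysed here.

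The deposited values are log2 expression values, 1 per probe set and sample, which the authors made with RMA, per the submitters' processing notes. As generally defined, RMA corrects background, applies quantile normalization across arrays and summarises the probes of a probe set. The version, the software and the probe set definition are not given in the sources used here. Because RMA shrinks differences of dim probes, a fold change of a weakly expressed gene is understated. Scanner files and detection calls were not used here, and no scan date or batch is given in the sources used here. The table held 38535 probe sets with 0 missing values, and all its columns mapped to samples by title.

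The 96 AFFX control probe sets were left out, and 38439 were tested. Gene names came from the platform annotation, with symbols updated through Entrez IDs to the RefSeq table of GRCg7b, which changed 0 symbols. Of the tested probe sets 27168 had 1 gene symbol, 177 had several and 11094 had none here. Of those with 1 symbol, 26853 had an Entrez ID in the RefSeq table and 315 kept the annotation's symbol. Each of 13009 genes was represented by its probe set with the highest mean over the 6 samples, and values are those of that probe set unless stated. Probe sets of 1 gene often differed in the size of a change. Of 7334 genes with 2 or more probe sets, 7 had called probe sets in both directions, and none of these is named in the text. The annotation names no genome build, so no coordinates are given, and the assembly was used only for names, chromosomes and the order of neighbouring genes. Annotation was joined in Python 3.11.15, and plots were drawn with matplotlib.

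Each probe set was fitted in R 4.3.3 with limma 3.58.1 (lmFit with the group as the only term, and eBayes, two-sided), and p-values were adjusted by Benjamini-Hochberg over the 38439 probe sets. The threshold was an adjusted p of 0.05. Standard errors are limma's moderated ones. The median SD within a group was 0.105 for wild type and 0.124 for Pax5-deficient samples on the log2 scale. The median log2 fold change of all probe sets was 0.03, and changes are given without subtracting it.

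The background of an array was set, after the data were seen, at the 95% point of 689 probe sets for virus genomes, on average 3.83 on the log2 scale. A gene with all 3 samples of a group at or under it is called at background there. Its fold is then a bound, from the mean of the other group against the mean of the higher of background and own value in each sample. No depth or count interval applies to arrays.

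20 gene lists with 723 members were fixed before the data were examined, as were the tests, the other processing choices and the rule for naming genes. The lists cover PAX5-activated and PAX5-repressed genes, B cell receptor signalling, B lineage transcription factors, plasma cell genes, immunoglobulin gene diversification and DNA repair, MHC class II presentation, chemokine receptors and adhesion, MAPK, calcium and NF-kB pathway components, interferon response, apoptosis regulators, cell cycle genes, cytosolic ribosomal proteins, protein folding and export in the endoplasmic reticulum, cholesterol synthesis and uptake, glycolysis, and markers of myeloid, T lineage, erythroid and thrombocyte, and fibroblast and stromal cells. Lists share some genes, such as EBF1, which is both a B lineage transcription factor and a PAX5-activated gene. They were tested with limma's camera at its preset correlation of 0.01, adjusted over the 20 lists, with an estimated correlation and fry beside it. List symbols were matched to gene symbols, and BLNK was matched to SH2D6 by a synonym in the RefSeq table, a choice made after the data were seen. The rule for named genes took the 16 genes of a marker list, the 12 largest rises and 12 largest falls among genes that passed with no overlap between the groups, and up to 4 members of each list with the smallest adjusted p. It gave 106 genes, of which 84 passed. Genes named outside the rule are said to be so where they appear, apart from ID3, SEC62 and SSR3, which were named after their values were seen.

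The fit was tested on simulated data for this comparison, over 38439 probe sets with the spread of the real samples. It recovered 10.4% of changes of 0.5, 71.6% of changes of 1 and 92.4% of changes of 2 on the log2 scale. The 67, 67 and 66 changed probe sets were drawn from those with a mean log2 value over 5. Of 119 calls 3 were false. The real data gave 4085 calls, so the Benjamini-Hochberg adjustment was less strict there, and these shares do not carry over to it. When 1 list was shifted, 1 list passed camera. Simulated genes varied independently, so that run could not show the list calls that correlated genes can give at the preset correlation.

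Alternatives were a replicate block, quantile normalization or median centring of the deposited values, filters on dim probe sets, eBayes with trend and with robust priors, array weights, each sample left out in turn, a test against a change of 0.5, the mean of all probe sets of a gene, and the set tests named above. The chromosome analysis and the fit without genes of chromosomes 9, 10 and 21 were added after the data were seen, as was the match of list members through all synonyms. Chromosomes with at least 20 genes of mean log2 value over 5 were used. Random gene lists (10000 per chromosome) were matched on mean level, and shares of genes carry 95% Clopper-Pearson intervals, which treat genes as independent.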

Results

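Gene expression was measured in DT40 cells, a chicken B cell line from the bursa of Fabricius in which genes are readily disrupted by homologous recombination. Cells whose PAX5 gene had been targeted with 2 selection cassettes were set against the wild-type line, with 3 samples in each group. PAX5 is a transcription factor that B cells need to keep their identity, and the comparison asks which transcripts differ when it is lost. The targeted cells also went through transfection and selection of clones. Effects of those steps on any gene or list cannot be told apart from effects of the loss of PAX5 in this design. Each sample was hybridised to 1 Affymetrix chicken array, and 38439 probe sets were tested after the array controls were set aside. The array-wide median was between 3.948 and 4.016 on the log2 scale in the 6 samples. Between 52.4% and 55.04% of probe sets lay above the background level of their array. Correlations across probe sets were 0.9946 to 0.9959 between wild-type samples, 0.9909 to 0.9936 between Pax5-deficient samples and 0.9781 to 0.9806 between the groups. These run across probe sets, which are not independent replicates. The number of arrays limits the precision. The design text calls the samples biological replicates. Nothing says that they came from separate cultures or clones, so p-values measure the spread between these samples.

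The targeted gene was examined first. PAX5, on chromosome Z, has 4 probe sets on the array. The 1 that passed fell by 0.84 ± 0.14 on the log2 scale (SE, n = 3 per group; limma, Benjamini-Hochberg adjusted p = 0.00483), from 4.42 ± 0.12 to 3.58 ± 0.26 (mean ± SD). It was above background in the wild-type samples, with values of 4.55, 4.41 and 4.30. It was at background in all 3 Pax5-deficient samples, with values of 3.86, 3.55 and 3.34, so the fall was at least 1.47-fold. The brightest of the 4, which represents the gene in the counts of genes, had a log2 difference of 0.24 ± 0.09, which did not pass (limma adjusted p = 0.136). The other two were at background in every sample. Where these probe sets lie relative to the replaced part of the gene is not given in the sources used here, and a probe set outside that part checks nothing about the disruption.

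The 12 largest falls in Pax5-deficient cells, ranked by fitted log2 change on the brightest probe sets, included VPREB3, EBF1 and CD72 of the list of genes that PAX5 is known to activate. RGCC, a regulator of the cell cycle, fell by 7.31 ± 0.28 on the log2 scale (SE, n = 3 per group), or 159-fold, on its brightest probe set and 19.9-fold on another. VPREB3, a B lineage protein that associates with immunoglobulin light chains, fell by 6.60 ± 0.20, or 96.7-fold. EBF1, a transcription factor of early B cell commitment, fell from 8.67 ± 0.04 (SD) to background in all 3 samples, at least 27.9-fold, and at least 9.89-fold on another probe set. TNFSF13B, which encodes the B cell survival factor BAFF, also fell to background, at least 39.2-fold, and at least 17.2-fold and 14.7-fold on others. CD72, a coreceptor of B cells, fell 16.2-fold, to 4.55 ± 0.12 (SD), and on another probe set it fell by 1.98 ± 0.22 (SE) on the log2 scale.

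Among the 12 largest falls were also RBM38, an RNA-binding protein, at least 84.8-fold, and HVCN1, a proton channel, 74.5-fold. Other probe sets of RBM38 fell 41.7-fold and 2.52-fold, and 1 had a log2 difference of 0.03 ± 0.11, which did not pass. HVCN1 fell 29.9-fold on another. LBH fell 42.8-fold, RGS20 17.8-fold and WBSCR17 32.7-fold, the last 2.41-fold on another probe set. VAT1 fell to background, at least 22.2-fold, while another of its probe sets did not pass (-0.46 ± 0.20). EMB fell 35.3-fold, with a wide spread in the Pax5-deficient samples (4.12 ± 1.04, SD). The largest fitted rise was that of NDFIP1, an adaptor of ubiquitin ligases, by 4.72 ± 0.16 on the log2 scale, or 26.4-fold, on the probe set that represents it, while of its others 1 rose from background, at least 5.70-fold, 1 rose by 0.64 ± 0.14 and 1 did not pass (0.44 ± 0.13). ACHE, which encodes acetylcholinesterase, rose 19.4-fold on its brightest probe set, while of its other probe sets 1 passed, rising from background at least 1.13-fold. BHLHE41, a transcriptional repressor, rose 9.68-fold, and VCL, which encodes the adhesion protein vinculin, 8.03-fold, with 3.69-fold and at least 5.01-fold on other probe sets of VCL. CHIR-IG1-5, of a family of immunoglobulin-like receptors, rose 18.9-fold, and by 2.29 ± 0.36 and 2.43 ± 0.62 on other probe sets, and near-identical copies of these genes make the assignment of its signal uncertain. KCNMB1 rose 16.7-fold, CARD19 7.40-fold and HSPA2 7.25-fold. TMEM74 and MRGPRH rose from background, at least 7.33-fold and 5.28-fold, and another probe set of TMEM74 rose 1.93-fold. KLF13, on chromosome 10, rose from background to 6.15, 7.50 and 5.31 in the 3 samples, at least 5.76-fold (at least 3.82-fold without Pax5-deficient replicate 2), while others that passed rose 2.95-fold and 1.73-fold. CHST2, on chromosome 9, rose 6.50-fold. Some calls of the other probe sets were lost when 1 sample was left out. That held for WBSCR17 without wild-type replicate 2 or 3 or Pax5-deficient replicate 3 (limma adjusted p = 0.0752, 0.052 and 0.0658). It held for the NDFIP1 rise of 0.64 without wild-type replicate 2 or 3 or Pax5-deficient replicate 1 (0.0849, 0.0726 and 0.0531). The KLF13 rise of 2.95-fold was lost without any of wild-type replicates 1, 2 and 3 (0.0942, 0.104 and 0.0756) and that of 1.73-fold without replicate 2 or 3 (0.066 and 0.0674). The second ACHE call was lost when any sample except Pax5-deficient replicate 2 was left out (0.0593 to 0.149). The CHIR-IG1-5 rise of 2.43, with a wide spread in the Pax5-deficient samples (7.10 ± 1.57, SD), was 1.53 ± 0.15 without Pax5-deficient replicate 2, and its call was lost without any of the wild-type replicates or without Pax5-deficient replicate 3 (0.0523 to 0.144). The highest adjusted p among the brightest probe sets of these 24 genes was 0.00469, for KLF13 (limma, Benjamini-Hochberg).

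**Figure D1:**
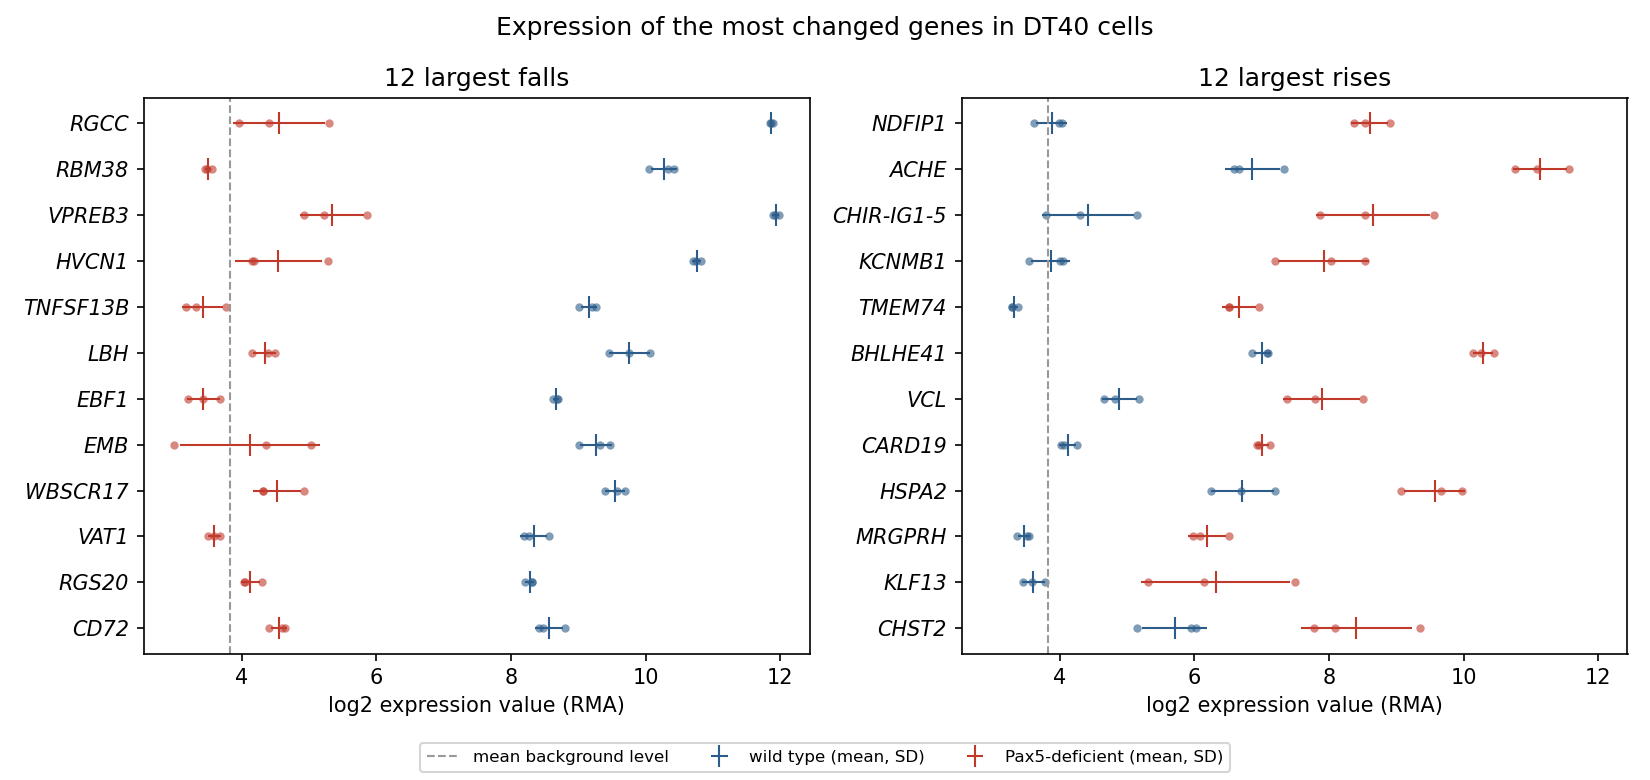
Log2 expression values (RMA, horizontal axis) of the 12 genes with the largest falls and the 12 with the largest rises. Points are the 3 samples of each group, vertical marks with bars are means ± SD, and the dashed line is the mean background level of 3.83. The 3 wild-type and 3 Pax5-deficient samples do not overlap for any of these genes, as the rule for choosing them required. RBM38, TNFSF13B, EBF1 and VAT1 lie at background in the Pax5-deficient samples.

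In all, 4085 of 38439 probe sets passed an adjusted p of 0.05 in limma, of which 1509 were higher and 2576 lower in Pax5-deficient cells. With a change of at least 2-fold added, 977 passed, 266 higher and 711 lower. Represented by 1 probe set each, 2049 of 13009 named genes passed, 782 higher and 1267 lower, so that 61.8% of them were lower. Quantile normalization of the deposited values moved that share to 51.8%, with 1059 genes higher and 1138 lower. The samples of the groups did not overlap for 4551 genes (35% of those measured), where chance gives 10%. Without wild-type replicate 2 the counts were 2490 probe sets and 1286 genes. With the change tested against 0.5 on the log2 scale, 780 probe sets passed.

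Of the 16 marker genes chosen before the data were examined, mostly of the B cell and plasma cell states, 14 were measured. The others were not analysed here. Besides EBF1, BCL6, a repressor that maintains germinal centre B cells, fell by 2.82 ± 0.16 on the log2 scale (SE, n = 3 per group). CD79B, a signalling chain of the B cell receptor, fell by 2.29 ± 0.11. The adaptor BLNK, listed as SH2D6 in the reference table and matched through a synonym, fell by 1.20 ± 0.18. IRF8 and IKZF3 fell by 0.73 ± 0.19 and 0.65 ± 0.15, and another probe set of IKZF3 did not pass (-0.23 ± 0.14). The IRF8 call was lost without any of the wild-type replicates 1, 2 and 3 (limma adjusted p = 0.112, 0.164 and 0.0771) or without Pax5-deficient replicate 1 or 3 (0.112 and 0.137). The IKZF3 call was lost without wild-type replicate 1 or 2 (0.0944 and 0.11) or without Pax5-deficient replicate 2 or 3 (0.0599 and 0.0748). Both calls were also lost after quantile normalization, and the IKZF3 call with the mean of its probe sets. The plasma cell regulators IRF4, XBP1 and PRDM1 did not pass, with log2 differences of 0.29 ± 0.11, 0.03 ± 0.08 and 0.22 ± 0.14. PRDM1 was at background in both groups, so its value gives no fold. JCHAIN, the joining chain of secreted immunoglobulin, had a difference of 0.25 ± 0.13, at a high level in wild-type cells (12.77 ± 0.23, SD). IKZF1, SYK and CSF1R had differences of 0.44 ± 0.13, 0.29 ± 0.11 and -0.03 ± 0.15, and none passed.

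Genes of B cell receptor signalling fell as a group. Of 33 measured members, 18 fell, none rose and 15 did not pass, and 21 were lower and 1 higher when adjusted over the list alone. RASGRP3, an activator of Ras, fell by 2.63 ± 0.16 on the log2 scale (SE, n = 3 per group), the kinases LYN and BTK by 1.70 ± 0.11 and 0.87 ± 0.09, and CD79B by the 2.29 given above. The list passed limma's camera with its preset correlation (Benjamini-Hochberg adjusted p = 1.14e-08; adjusted p = 0.175 with an estimated correlation). Among 20 measured genes that PAX5 is known to activate, 9 fell, 1 rose and 10 did not pass, and the counts were 10 lower and 5 higher when adjusted over the list alone. EBF1, CD72, VPREB3 and RASGRP3 led the falls, and ID3, an inhibitor of E proteins, was the gene that rose, by 1.10 ± 0.11. That list passed camera too (adjusted p = 0.0117; adjusted p = 0.294 with an estimated correlation). Among 16 measured genes that PAX5 is known to repress, none rose and 15 did not pass, and EMB, an adhesion molecule, fell. The same 1 gene was lower when adjusted over the list alone, and camera did not pass (adjusted p = 0.884). SDC1, CD244 and JCHAIN had log2 differences of 0.26 ± 0.13, -0.19 ± 0.09 and 0.25 ± 0.13.

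Of 34 measured B lineage transcription factors, 12 fell, 4 rose and 18 did not pass, and adjusted over the list alone 12 were lower and 8 higher. FOXO1 and RUNX1 fell by 2.42 ± 0.19 and 1.73 ± 0.14 on the log2 scale (SE, n = 3 per group) beside EBF1 and BCL6, and RUNX1 by 0.67 ± 0.12 on another probe set. The list did not pass camera (adjusted p = 0.157), and its median was 0.04 while its mean and test were downward. Genes of the cell cycle fell where they passed: 16 of 49 measured members fell, none rose and 33 did not pass, and adjusted over the list alone 22 were lower and 3 higher. E2F1, an activator of S phase genes, fell by 1.10 ± 0.09, CCNE2 by 1.32 ± 0.13, and the replication factors ORC1 and CDC45 by 1.03 ± 0.12 and 0.95 ± 0.12. The list passed camera (adjusted p = 4.19e-07; adjusted p = 0.595 with an estimated correlation). Of 41 measured genes of immunoglobulin gene diversification and DNA repair, 11 fell, 3 rose and 27 did not pass, with 13 lower and 4 higher when adjusted over the list alone. UNG, the glycosylase that removes uracil from DNA, fell by 1.78 ± 0.10, BRCA2 by 1.13 ± 0.13, RAD54L by 0.72 ± 0.11 and the translesion polymerase REV1 by 0.62 ± 0.09. That list passed camera (adjusted p = 0.0254; adjusted p = 0.65 with an estimated correlation), but not without wild-type replicate 3 (adjusted p = 0.0639), without Pax5-deficient replicate 1 (0.144), after quantile normalization (0.0718) or without probe sets under the median level (0.114), and it did not pass limma's fry (adjusted p = 0.0587).

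None of 59 measured cytosolic ribosomal protein genes passed singly, also when adjusted over the list alone. Their median difference was -0.11 on the log2 scale, and the list passed camera (adjusted p = 0.00567; adjusted p = 0.852 with an estimated correlation). The call was lost without Pax5-deficient replicate 3 (adjusted p = 0.111), after quantile normalization (0.0718) and without probe sets under the median level (0.0544), and the list did not pass fry (adjusted p = 0.178). RPS29 and RPS28 had differences of -0.33 ± 0.10 and -0.36 ± 0.11 (SE, n = 3 per group). None of the 5 list calls held with an estimated correlation, where 2 lists had an unadjusted p under 0.05. Limma's fry, which asks whether the genes of a list move one way, passed 6 lists: B cell receptor signalling, PAX5-activated genes and the cell cycle, and 3 that camera did not pass. Those were B lineage transcription factors (adjusted p = 7.35e-05), apoptosis regulators (0.0058) and chemokine receptors and adhesion (0.03). Other divisions of the 6 samples into 3 and 3 gave up to 6 list calls with camera's preset correlation. Each compares mixed groups that keep part of the genotype difference, so these counts do not estimate false list calls.

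**Figure D2:**
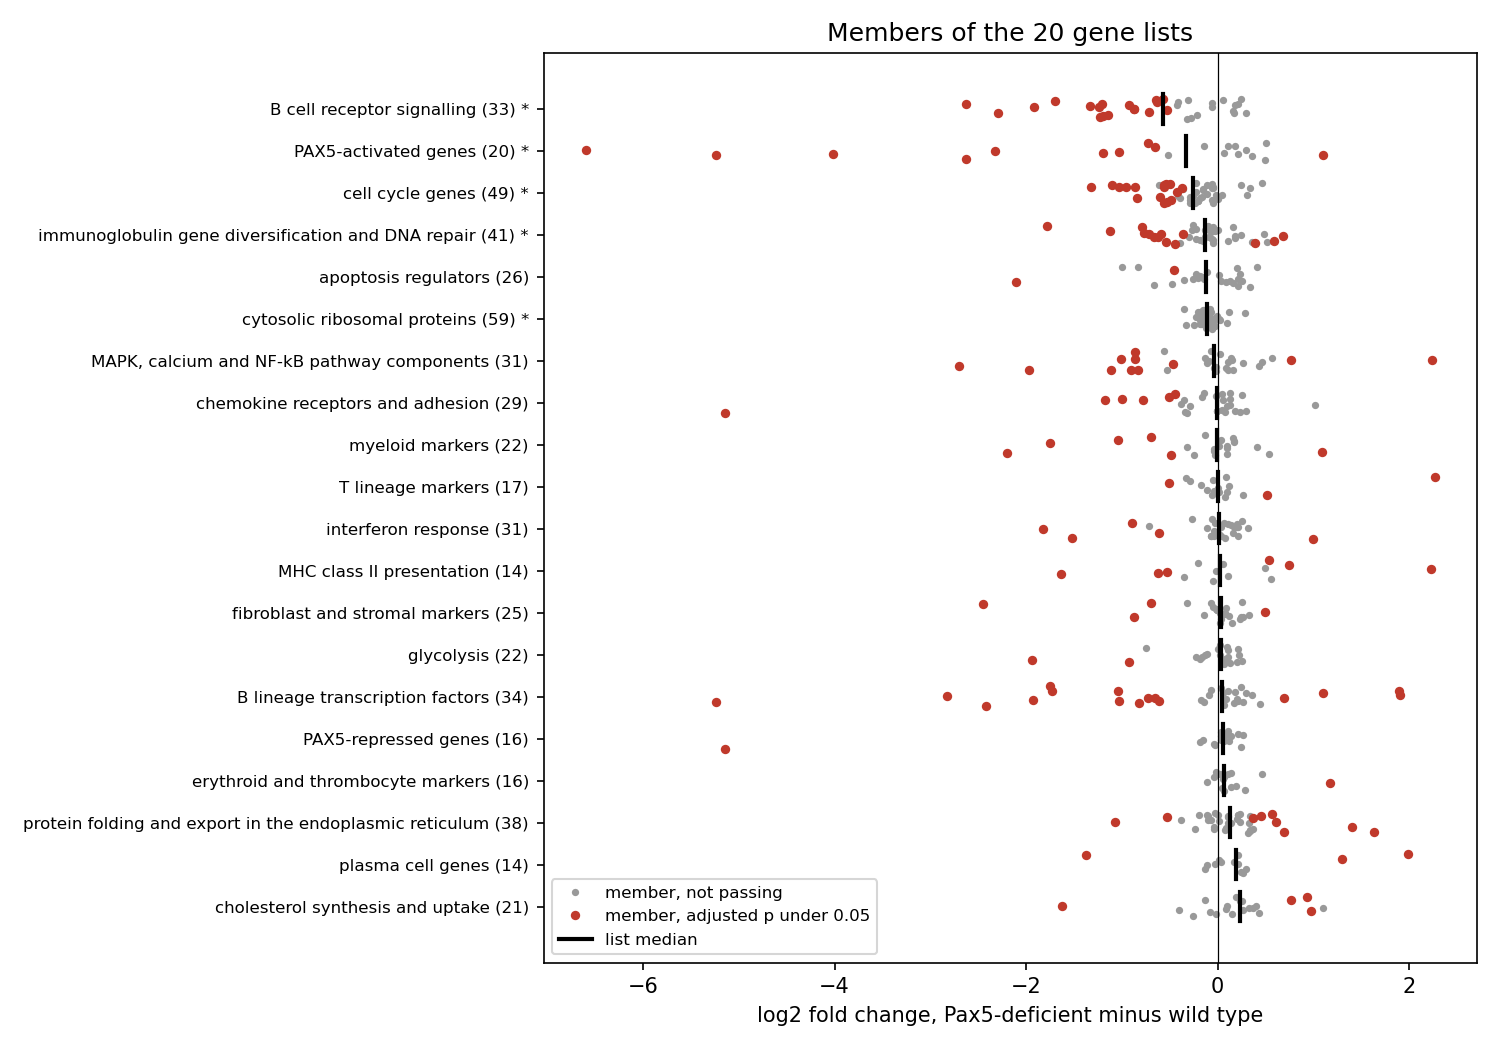
Log2 fold change (Pax5-deficient minus wild type, horizontal axis) of each measured member of the 20 gene lists, with the number of members in brackets. Red points passed an adjusted p of 0.05, grey points did not, black bars are list medians, and a star marks the 5 lists that passed camera with its preset correlation. The medians of the starred lists lie below 0, and that of B cell receptor signalling is -0.57.

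Genes of protein folding and export in the endoplasmic reticulum went both ways. Of 38 measured members 7 rose, 2 fell and 29 did not pass, and 8 were higher and 2 lower when adjusted over the list alone. DNAJB11, SEC24D and CALR rose by 1.64 ± 0.18, 1.40 ± 0.18 and 0.69 ± 0.10 on the log2 scale (SE, n = 3 per group), and ERO1B fell by 1.08 ± 0.09. The list did not pass camera (adjusted p = 0.0692), but passed without wild-type replicate 2 (0.0276), without Pax5-deficient replicate 1 (0.0467) or 3 (0.0245), after quantile normalization (0.0297), with the mean of probe sets (0.0137) and with a variance trend in eBayes (0.045). With an estimated correlation its adjusted p was 0.663. Of the 7 that rose, DNAJB11, SEC62 and SSR3 lie on chromosome 9, whose genes had a higher median in all 3 Pax5-deficient samples. Of 14 measured plasma cell genes 2 rose, 1 fell and 11 did not pass, also when adjusted over the list alone (camera adjusted p = 0.2). CREB3L2 and TXNDC5 rose by 1.99 ± 0.18 and 1.29 ± 0.15, and DERL3 fell by 1.38 ± 0.09. Another probe set of CREB3L2 rose by 0.74 ± 0.11, and the calls of 3 more were lost without 1 or another of the 6 samples (limma adjusted p = 0.0509 to 0.101). Of 14 measured genes of MHC class II presentation, 3 rose, 3 fell and 8 did not pass (5 higher and 4 lower when adjusted over the list alone; camera adjusted p = 0.884). CD83 rose from background, at least 3.58-fold, BLB1 rose by 0.54 ± 0.10 on its brightest probe set and by 2.69 ± 0.22 and 1.88 ± 0.18 on others that passed, and the protease CTSS fell by 1.64 ± 0.15.

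Of 31 measured components of MAPK, calcium and NF-kB pathways, 9 fell, 2 rose and 20 did not pass (10 lower and 3 higher when adjusted over the list alone; camera adjusted p = 0.129, and 0.0495 without Pax5-deficient replicate 1; adjusted p = 0.65 with an estimated correlation). NFKBIZ fell by 1.97 ± 0.23 on the log2 scale (SE, n = 3 per group) and TRAF3 by 1.11 ± 0.12, while the calcium pump ATP2B4 rose by 2.24 ± 0.21 on its brightest probe set and by 0.55 ± 0.14 and 0.44 ± 0.11 on others, whose calls were lost without 1 or another of the 6 samples (limma adjusted p = 0.06 to 0.13). Of 29 measured chemokine receptors and adhesion molecules 6 fell, none rose and 23 did not pass (9 lower and 1 higher when adjusted over the list alone). CXCR5, a homing receptor of B cell follicles, fell by 1.18 ± 0.14, CXCR4 by 0.77 ± 0.09 and ITGA6 by 1.00 ± 0.09 (by 0.44 ± 0.09 on another probe set, a call lost without wild-type replicate 1 or 3, limma adjusted p = 0.0687 and 0.063). Camera gave that list an adjusted p of 0.0908, which was 0.0456 without wild-type replicate 2 and 0.0432 without Pax5-deficient replicate 1 and 0.0248 with the mean of probe sets (adjusted p = 0.65 with an estimated correlation over all samples). Of 31 measured interferon response genes 4 fell, 1 rose and 26 did not pass, also when adjusted over the list alone (camera adjusted p = 0.884). TLR7 and SOCS1 fell by 1.52 ± 0.15 and 1.83 ± 0.20, and IRF7 rose by 1.00 ± 0.16. Among 26 apoptosis regulators 2 fell and 24 did not pass, also when adjusted over the list alone (camera adjusted p = 0.388), and BOK fell by 2.10 ± 0.11, while its other probe set did not pass (-0.47 ± 0.16). Of 22 glycolysis genes 2 fell and 20 did not pass, also when adjusted over the list alone (camera adjusted p = 0.884): the lactate transporter SLC16A3 fell by 1.94 ± 0.17 and PDK3 by 0.92 ± 0.09. Of 21 genes of cholesterol synthesis and uptake 3 rose, 1 fell and 17 did not pass (5 higher and 1 lower when adjusted over the list alone; camera adjusted p = 0.129). PMVK rose by 0.97 ± 0.09 and INSIG2, which restrains the pathway, fell by 1.62 ± 0.11. The cholesterol list passed without wild-type replicate 3 (adjusted p = 0.000336) and without Pax5-deficient replicate 3 (0.0245), but had an adjusted p = 0.925 with an estimated correlation over all samples.

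Markers of other cell types did not move together. Of 22 measured myeloid markers 5 fell, 1 rose and 16 did not pass (camera adjusted p = 0.368). SPI1 and CEBPB, which B cells also express, fell by 1.04 ± 0.12 and 1.75 ± 0.19 on the log2 scale (SE, n = 3 per group), NCF4 fell by 2.20 ± 0.24, and CSTA rose from background, at least 1.53-fold. Of 17 T lineage markers 2 rose, 1 fell and 14 did not pass (camera adjusted p = 0.884), and CD247, a signalling chain of the T cell receptor, rose by 2.27 ± 0.27. Adjusted over the list alone, 2 T lineage markers were higher and 2 lower. Of 16 erythroid and thrombocyte markers TFRC, on chromosome 9, rose by 1.18 ± 0.13, and 15 did not pass (camera adjusted p = 0.129). HBA1 had a difference of 0.46 ± 0.14. Of 25 fibroblast and stromal markers 1 rose, 3 fell and 21 did not pass (camera adjusted p = 0.932), with falls of 2.45 ± 0.09 for TIMP2 and 0.88 ± 0.11 for VIM. COL1A2, a collagen chain, rose by 0.50 ± 0.10 on the probe set with the highest mean over the 6 samples. That call was lost without wild-type replicate 2 (limma adjusted p = 0.0511). On others COL1A2 rose by 4.46 ± 0.19, 0.96 ± 0.13 and 0.81 ± 0.12, and 1 more rose from background, at least 11.2-fold. In Pax5-deficient samples the probe sets with the largest rises, at 8.56 and 7.27, lay above the first one, at 6.81. The remaining COL1A2 probe sets were at background in both groups. For the myeloid, erythroid and stromal lists the counts were identical when adjusted over the list alone. The median, mean and test differed in sign for 5 of the 20 lists: B lineage transcription factors, PAX5-repressed genes, fibroblast and stromal markers, glycolysis and interferon response. The log2 signal of the 3' actin controls exceeded that of the 5' controls by 1.6, 1.55 and 1.53 in the wild-type samples and by 1.37, 1.5 and 1.19 in the Pax5-deficient samples. For the GAPDH controls that difference was -0.362, -0.286 and -0.334 in the wild-type samples and -0.328, -0.285 and -0.355 in the Pax5-deficient samples.

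The genes of some chromosomes also differed together between the samples. Chromosomes were taken from the GRCg7b assembly, and medians were taken over genes with a mean log2 value over 5. On chromosome 9 the median log2 fold change of 210 genes was 0.40, and on chromosome 21 that of 112 genes was 0.34, while the highest median of another chromosome was 0.077. Against the wild-type mean, the genes of chromosome 9 had medians of 0.37, 0.45 and 0.38 in Pax5-deficient replicates 1, 2 and 3. Those of chromosome 21 had medians of 0.63, -0.06 and 0.59, and those of chromosome 10 had medians of -0.07, 0.36 and -0.08. The Pax5-deficient samples were thus not alike. Genes of any level were counted next. Of the 780 that rose and had a chromosome entry, 132 lay on chromosomes 9 and 21 (16.9%). That entry can be unknown, as for ACHE. Of all 1267 that fell, 18 lay there. Of all 13009 genes, 599 were placed on these chromosomes. Camera was run over all genes of each chromosome, dim ones included. With the preset correlation camera gave adjusted p = 3.59e-09 for chromosome 9 and 5.73e-05 for chromosome 21. Neither passed camera with an estimated correlation (adjusted p = 0.0899 and 0.961). BCL6 and BOK lie on chromosome 9 and fell, against the direction of that chromosome, and TFRC, DNAJB11 and CHST2 lie there and rose. With the genes of chromosomes 9, 10 and 21 left out, a choice made after these values were seen, 3795 probe sets passed, 1268 higher and 2527 lower, and 636 genes were higher and 1239 lower.

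**Figure D3:**
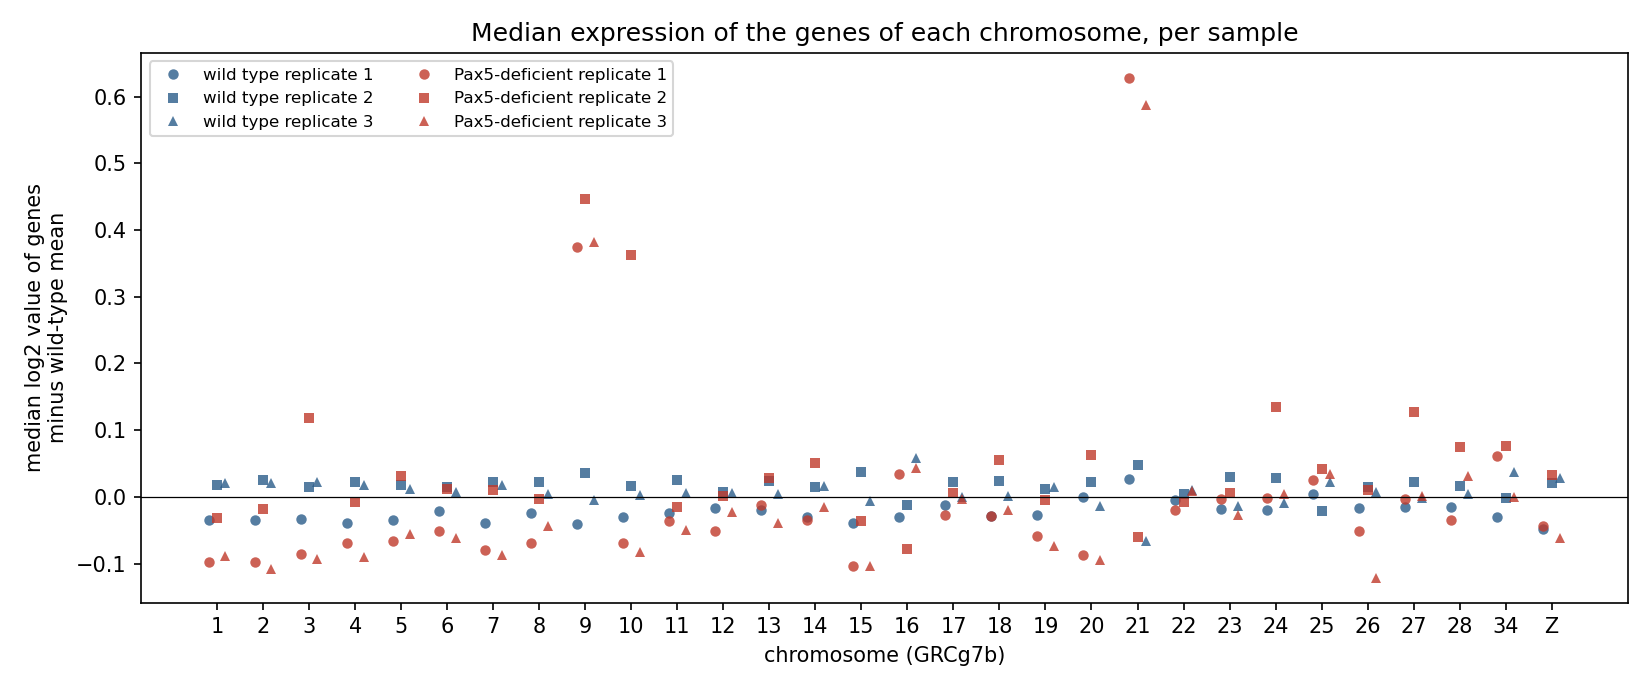
Median over the genes of each chromosome (horizontal axis, GRCg7b) of the log2 value minus the wild-type mean (vertical axis), with 1 point per sample and genes with a mean log2 value over 5. Chromosome 9 is raised in all 3 Pax5-deficient samples, chromosome 21 in replicates 1 and 3 (0.63 and 0.59) and chromosome 10 in replicate 2 (0.36).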

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

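Both tests in this part were chosen after the result was seen. A reporter probe set, RPTR-Gga-U57609-2_s_at, stood out among probe sets for foreign sequences that no comparison of genes uses. It was at background in the wild-type samples (3.67, 3.33 and 3.11 on the log2 scale) and at 9.86, 9.64 and 9.88 in the Pax5-deficient samples. The log2 difference was 6.42 ± 0.14 (SE, n = 3 per group; limma adjusted p = 1.03e-07), at least 64-fold.

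A general rise of signal on foreign-sequence probe sets is argued against, since the other reporter probe sets had a median log2 difference of 0.058. Of these 1 more passed, RPTR-Gga-AF403737-1_at, higher by 0.47 ± 0.08 (limma adjusted p = 0.00736) and at background in all 6 samples, and none was above it. A candidate explanation is sequence carried into the cells with the selection cassettes. The probe set was above background in 0 of the 3 wild-type samples, but this is the observation itself and lends that explanation no support. Which sequence the probe set stands for is not given in the sources used here, so a sequence of the cassettes and one that entered the cells in another way cannot be told apart. No biological explanation was tested.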

How the results depend on the processing

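Alternatives were planned before the data were examined, except the fit without genes of chromosomes 9, 10 and 21 and the wider match of list members. No result reversed. The number of PAX5 probe sets that passed stayed at 1 in all fits that gave it. Leaving out 1 sample at a time gave 2490 to 4172 probe sets, 907 to 1013 of at least 2-fold, 1286 to 2097 genes and 5 to 7 lists. The lowest counts of probe sets and genes came without wild-type replicate 2, and the cause was not tested. Of the 2490 probe sets, 2444 were among the 4085. Testing the change against 0.5 on the log2 scale left 780 probe sets, as a stricter test must. Without probe sets under the median level 3 lists passed, and the cause was not tested. With an estimated correlation 0 lists passed in camera, 2 at an unadjusted p under 0.05. Across 1050 refits of named genes, 10 lost their call and 23 gained one. In 636 refits without 1 sample, 41 lost the call and 4 gained it. These losses fell on 11 of the 84 genes: BIRC2, CD3E, CD8A, COL1A2, COL5A2, DMA, FDFT1, HSD17B7, IFNGR1, IKZF3 and IRF8. Array signal limits the rest: 14923 probe sets were at or under background in all 6 samples.

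The replicate numbers gave no clear pairing of the samples. Deviations of same-numbered samples from their group means correlated at 0.115, 0.0724 and -0.00729. Wild-type replicates 1 and 2 correlated best with the same-numbered Pax5-deficient samples, and wild-type replicate 3 with Pax5-deficient replicate 2. Correlations this weak leave a pairing open. With the replicate number as a block 4116 probe sets passed, 3654 of them among the 4085.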

Other observations

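Genes outside the fixed lists were looked at after their values were seen, all within the same fit. PAX3, a relative of PAX5 on chromosome 9, fell from 7.08 ± 0.16 to 4.33 ± 0.09 on the log2 scale (SD, n = 3 per group), by 2.75 ± 0.11 (SE), and was the 1 gene that passed among 6 measured PAX genes by the probe set that represents each, while PAX5 passed on a dimmer probe set. Among 10 measured antagonists of Wnt signalling 3 fell and none rose, while 1267 of all 13009 genes fell. SFRP1, SFRP2 and DACT2 fell by 3.16 ± 0.19, 3.21 ± 0.14 and 3.02 ± 0.32. Other families looked at were histones and heat shock proteins with DnaJ. Of 11 measured histone genes 3 fell and none rose. Of 61 measured heat shock and DnaJ genes 9 rose and 4 fell. All 4 measured CHIR genes, which encode immunoglobulin-like receptors, rose. CHIR-B3 rose by 2.65 ± 0.11 and CHIR-IG1-5 by 4.24 ± 0.43, and CHIR-B6 and CHIR-A2 rose from background, at least 3.26-fold and 1.58-fold. All 4 differences stayed above 0 after quantile normalization and with arrays centred on their medians. Their median of 2.44 moved only to 2.47 and 2.41, so crossing 0 was hardly possible and this tests little. The CHIR genes share near-identical sequence, so the 4 are not independent. Of 689 probe sets for virus genomes 1 passed: AY013303.CDS3.S1_s_at was at 9.78 ± 0.19 in wild-type and 10.48 ± 0.29 in Pax5-deficient samples (SD, n = 3 per group), higher by 0.69 ± 0.15 (SE; limma adjusted p = 0.0211).

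The tests of chromosomes and of the balance of falls and rises were planned before their outcomes were seen, with exceptions. The comparison among the Pax5-deficient samples, the parts of chromosome 9 alone and the quantile-normalized share among all calls were chosen after. The use of single samples to judge extra copies of both chromosomes was not in the plan. Chromosomes 9 and 21 were themselves picked as those with the highest medians in these values. Genes of chromosome 9 were higher as a block in all 3 Pax5-deficient samples, and those of chromosome 21 in replicates 1 and 3 but not in replicate 2. Of 322 genes on these chromosomes, 86% were higher in the means over samples (95% Clopper-Pearson interval 81.8% to 89.6%), against 46.9% on the others. The rise was thus spread over most genes, but chromosomes picked by their medians must have a high share. That share is therefore no separate test of a few strongly responding genes. In the planned test of scaling between arrays, the lower of the medians of these chromosomes after quantile normalization was 0.407, which went against scaling. Quantile normalization treats genes of like level alike on all chromosomes. It could hardly remove a difference between chromosomes, so that outcome tests little. Among random lists of matched level both chromosomes had a percentile of 100. The highest random medians were 0.0844 for chromosome 9 and 0.129 for chromosome 21. Brightness is argued against by these values, although chromosomes picked for their medians rank high by that choice. The planned test of extra copies of both chromosomes used means over samples, and its outcome went with extra copies. The lowest of the 8 part medians was 0.22, above the highest median of another chromosome, 0.077. Extra copies of both in all Pax5-deficient samples are still argued against by replicate 2, whose lowest part of chromosome 21 had a median of -0.234. An open candidate is chromosome content that differs among the samples. On chromosome 21 the parts in replicates 1 and 3 lay at least 0.505 above those in replicate 2, which restates the observation. On chromosome 10 the parts in replicate 2 lay at least 0.14 above those in replicates 1 and 3. For chromosome 9 extra copies in the Pax5-deficient cells, fewer in the wild type and an effect of genotype cannot be told apart. No DNA was measured. The lowest part of chromosome 9 in any Pax5-deficient sample was at 0.298. The bound for it, 0.628, was the median of chromosome 21 in replicate 1. Chromosome 21 belongs to the same observation, so that bound decides nothing. With chromosomes 10 and 21 set aside, the highest median of another chromosome in a single sample was 0.135, for chromosome 24 in Pax5-deficient replicate 2. A part of chromosome 34 with 12 genes reached 0.356 in Pax5-deficient replicate 1.

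More probe sets were lower than higher in Pax5-deficient cells. Among those of at least 2-fold the share lower was 72.8%, and 67.9% after quantile normalization, which argues against differing array distributions as the whole cause of that part. Among all calls the share was 63.1% (1509 higher and 2576 lower), and 54.3% after quantile normalization (1991 higher and 2366 lower). Array distributions may account for much of that part. Quantile normalization evens them whatever their cause, so technical and biological differences cannot be told apart by it. Whether higher copy number of chromosomes 9 and 21 acted through scaling was not settled: without their genes and with arrays centred on the rest 71.5% of calls were lower, but leaving out those genes (66.4%) and centring (68.1%) each raise the share by themselves. An effect of the loss of PAX5, which the design names, stays open as untested.

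The 6 samples allow 10 splits into 3 and 3, too few for a share under 0.05. The real split gave 4085 probe sets, 977 of at least 2-fold and 2049 genes, and each count was reached by 1 split, the real one, with a highest count of 0 in the others. For gene lists the real split gave 5, the highest other split gave 6, and 4 of the 10 splits gave 5 or more. Every other split mixes the genotypes unevenly. Part of the genotype difference then stays between its groups, and it also widens the spread within them. A count of 0 for probe sets and genes can follow from that spread, and the list counts do not estimate false list calls.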
